A study of Homo sapiens with 4 samples.

How the data were processed

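RNA immunoprecipitation sequencing (RIP-seq) was carried out on PANC-1 cells, a human pancreatic ductal carcinoma line, that stably overexpressed CGN (cingulin, a cytoplasmic protein of tight junctions). The series holds 4 samples, of which 2 are RNA pulled down with an antibody against CGN and 2 are input RNA of whole cells. No immunoprecipitate with a control antibody was used here, so the background of the pull-down is not measured. Per the labels' protocols, RNA was fragmented to short pieces, made into libraries with a NEBNext Ultra RNA kit and sequenced as paired reads on an Illumina instrument. Whether the 2 samples of a group came from separate cultures is not given in the sources used here. Per the submitters' processing notes, the build was hg38 and the tools included Trimmomatic 0.36, HISAT2 2.1.0 and HTSeq 0.6.0, which trim, align and count reads. The peak caller, its threshold, the use made of the input libraries and the way in which the 2 IP libraries were combined are not given in the sources used here.

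The one processed file is an annotated list of CGN IP peaks. Per the file header, each peak has a position, a count, a p-value, a region class, a transcript, a gene symbol with its NCBI gene number, and a transcript type. The deposited count is a whole number per peak, with no normalization and no value per library. The deposited p-value ran up to 0.0498, and whether it was adjusted for multiple tests is not stated. The list gives no fold enrichment and no input value, so the count is a level in the immunoprecipitate and not an enrichment over input. The planned tests of fold enrichment were therefore made on the log2 count, and the planned comparison of IP with input, the agreement of replicates and the base composition of peaks were not made. Only bins that passed the authors' threshold are listed, so their summed count of 191795 is not the depth of the libraries, which is unknown here. Counting precision is given as 95% exact Poisson intervals for counts and exact Clopper-Pearson intervals for shares. These intervals cover counting error only, since reads from amplified libraries without molecular identifiers are not independent molecules, and peaks and genes are not biological replicates.

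Peak starts were written 1-based. Genes were matched by NCBI gene number to the RefSeq gene table of the same build (GRCh38), which held 739 of the 741 genes. All 927 peaks of those genes lay on the table's span of their gene, and 4 genes have a newer symbol there; the file's symbols are used. No exon coordinates or genome sequence were used here. Region classes are the authors' own, and whether their exon class also holds untranslated exon sequence is not stated. The Illumina reads were not stated to be counted by strand, so overlapping and antisense genes cannot be told apart.

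Before the data were examined, 28 gene lists (776 entries, of which 5 were not matched to a gene), the tests, the alternatives and the rule for named genes were fixed. The rule names CGN, the 10 peaks of highest fold enrichment (here of highest count), the 10 of smallest p-value with ties broken by count (the same peaks), the 5 genes with most peaks (ties broken by their highest count) and up to 4 members per list with the highest count. For the 26 lists with at least 2 protein-coding members, the number of protein-coding members with a peak was set against all other protein-coding genes (20052 genes in all) by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists. This background includes genes that PANC-1 cells do not express, and no expression values were in the file, so a list of expressed genes can stand above it for that reason alone. Median log2 counts were compared between region classes of at least 10 peaks, and between list members and all other genes with a peak for lists of at least 3 such genes (strongest peak per gene), by two-sided permutation tests with 100000 resamples, Benjamini-Hochberg adjusted. The threshold was an adjusted p of 0.05.

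Alternatives were a count at or above the median, a p-value 10 times stricter than the largest, 1 peak per gene, exon and UTR peaks only, means in place of medians, and the mean over the peaks of a gene. Chosen after seeing the data were a background matched on genomic span (10000 random lists, 10 span bins) and a background of the other fixed lists. The tests were tested on simulated data. With 20052 genes, several lists of 20 or more genes were raised at once, and p was adjusted over the lists of that size. Raised lists were called in 35.2% of cases at a 4-fold higher share of genes with a peak and in 91.8% at an 8-fold higher share. A list that was not called may therefore still differ by several fold. A single raised list and smaller lists were not simulated for this test. For counts, 14 lists of the observed sizes (3 to 12 genes) were simulated among 741 genes with 1 list raised, and p was adjusted over the lists. A 4-fold higher count was called in 100% of 100 simulations, a 2-fold higher one in 44% and a 1.41-fold higher one in 10%, so count differences of 2-fold or less may have been missed. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.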

Results

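RIP-seq was used to ask which mRNAs are bound by CGN (cingulin), a tight junction protein, in PANC-1 pancreatic carcinoma cells that overexpress it. The 2 CGN IP and 2 input samples were represented by 1 list of CGN IP peaks without a value per library, so no value below has a replicate error and IP could not be set against input. The list held 929 peaks on 741 genes, 737 of them protein-coding, on 23 chromosomes. Counts ran from 116 to 1442 per peak, with a median of 167 and quartiles of 137 and 231, and summed to 191795.

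The strongest peaks lay on mRNAs of proteins of several cell compartments. HUWE1, a HECT-type E3 ubiquitin ligase, had the highest count, 1442 (95% exact Poisson interval 1369 to 1518), in an exon on chromosome X, bases 53591001 to 53591200. Next came both peaks of IGF2R, a lysosomal enzyme sorting receptor, with a count of 991 (930.3 to 1055) in an intron on chromosome 6, bases 160059001 to 160059200, and of 939 (880 to 1001) in an exon, bases 160047801 to 160048000. The intervals of the IGF2R peaks overlapped, and that of HUWE1 lay above both. PKM, the glycolytic pyruvate kinase, had a count of 906 (848 to 967) in an intron on chromosome 15, bases 72206801 to 72207000. PSMA7, a proteasome subunit, had 900 (842 to 961) in an exon on chromosome 20, bases 62139801 to 62140000. MYOF, a membrane repair protein, had 881 (824 to 941) in an exon on chromosome 10, bases 93379801 to 93380000. KMT2A, a histone methyltransferase, had 829 (774 to 887) in an exon on chromosome 11, bases 118488601 to 118488800, and CANX, a chaperone of the endoplasmic reticulum, had 795 (741 to 852) in an exon on chromosome 5, bases 179723601 to 179723800. RPL17, a protein of the large ribosomal subunit, had 709 (658 to 763) in an exon on chromosome 18, bases 49490401 to 49490600, and PRPF8, a core spliceosome protein, had 662 (613 to 714) in an exon on chromosome 17, bases 1683601 to 1683800. RPL17 has pseudogene copies, so its count is uncertain. The same can hold for other abundant genes, since 113 of 129 housekeeping, ribosomal and translation genes on the lists have a named pseudogene. These 10 peaks held 4.72% of the summed count.

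The authors' p-value followed the count alone. Among the 266 distinct counts, 1 (a count of 125) had more than 1 p-value, at the only peak wider than 200 bases, a 400-base exon peak of JMJD1C, a histone demethylase-like protein. Over the other 928 peaks p never increased with the count. The smallest p, 9.85e-13, was shared by the 17 peaks with counts of 541 or more. The p-value therefore ranks peaks as the count does and holds no separate measure of enrichment over input. The alternatives with a higher count and with a stricter p are thus cuts on the same ranking.

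**Figure D1:**
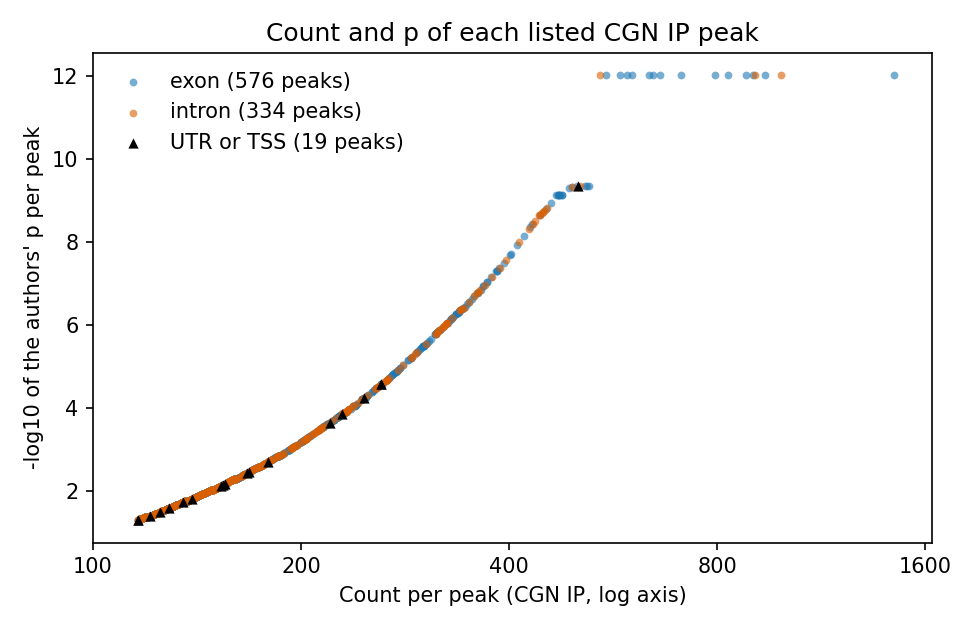
Each point is 1 of the 929 listed peaks, with its count on a log axis and the −log10 of the authors' p-value on the vertical axis, coloured by region class. The points of exon and intron peaks fall on one curve from a count of 116 upward, and the 17 peaks at the smallest p form a flat line at the top.

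CGN itself carried no listed peak, although the cells overexpressed it. The gene lies on chromosome 1, bases 151510170 to 151538692, and the nearest listed peak was 456770 bases away, in the 3' UTR of CDC42SE1. The paralog CGNL1 had no listed peak either. No bin under a count of 116 is listed, and the rule by which bins were listed is not known, so no limit on the CGN level follows.

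Most peaks were assigned to exons of mRNAs. Of the 929 peaks, 576 (62.0%, exact 95% interval 58.8 to 65.1) lay in exons, 334 (36.0%, 32.9 to 39.1) in introns, 14 (1.51%, 0.826 to 2.52) in 5' UTRs, 4 (0.431%, 0.117 to 1.10) in 3' UTRs and 1 at a transcription start site. The 3' UTR peaks were those of CDC42SE1 (count 261), IL6ST (155), RPL3 (139) and BTD (129), named after their values were seen. Transcripts of type mRNA held 835 peaks, other transcript variants of type misc_RNA 91, and long non-coding RNA 3. No peak lay on the mitochondrial genome. The median count was 171 for exon peaks and 160 for all others, a ratio of 1.07 (95% bootstrap interval 0.991 to 1.13, adjusted permutation p = 0.131). For intron peaks it was 160.5 against 170.0 (ratio 0.944, 0.892 to 1.02, adjusted permutation p = 0.131), and for 5' UTR peaks 167.5 against 166 (ratio 1.01, 0.833 to 1.37, adjusted permutation p = 0.946). No class passed the threshold, while with means in place of medians exon peaks were higher and intron peaks lower at an adjusted permutation p of 0.0496.

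Several genes carried more than 1 peak. One peak was listed for 600 genes, 2 or more for 141 and 3 or more for 29. UBR4, an E3 ubiquitin ligase of the N-degron pathway, had the most, with 9 peaks (7 exonic, 2 intronic) and counts from 126 to 411 along its 135757-base span on chromosome 1. PRKDC, the catalytic subunit of DNA-dependent protein kinase, had 6 peaks with counts from 177 to 646 on chromosome 8. The deubiquitinase USP9X on chromosome X (117 to 318) and the ubiquitin ligase HERC2 on chromosome 15 (131 to 204) had 5 each. HUWE1 had 4, of which the other 3 had counts of 160 to 378. No listed peaks touched each other, and 6 neighbouring pairs lay under 1000 bases apart. The median genomic span was 59378 bases for protein-coding genes with a peak and 23140 bases for those without. The share of genes with a peak was 0.15% in the shortest span decile, 7.88% in the ninth and 5.93% in the longest.

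**Figure D2:**
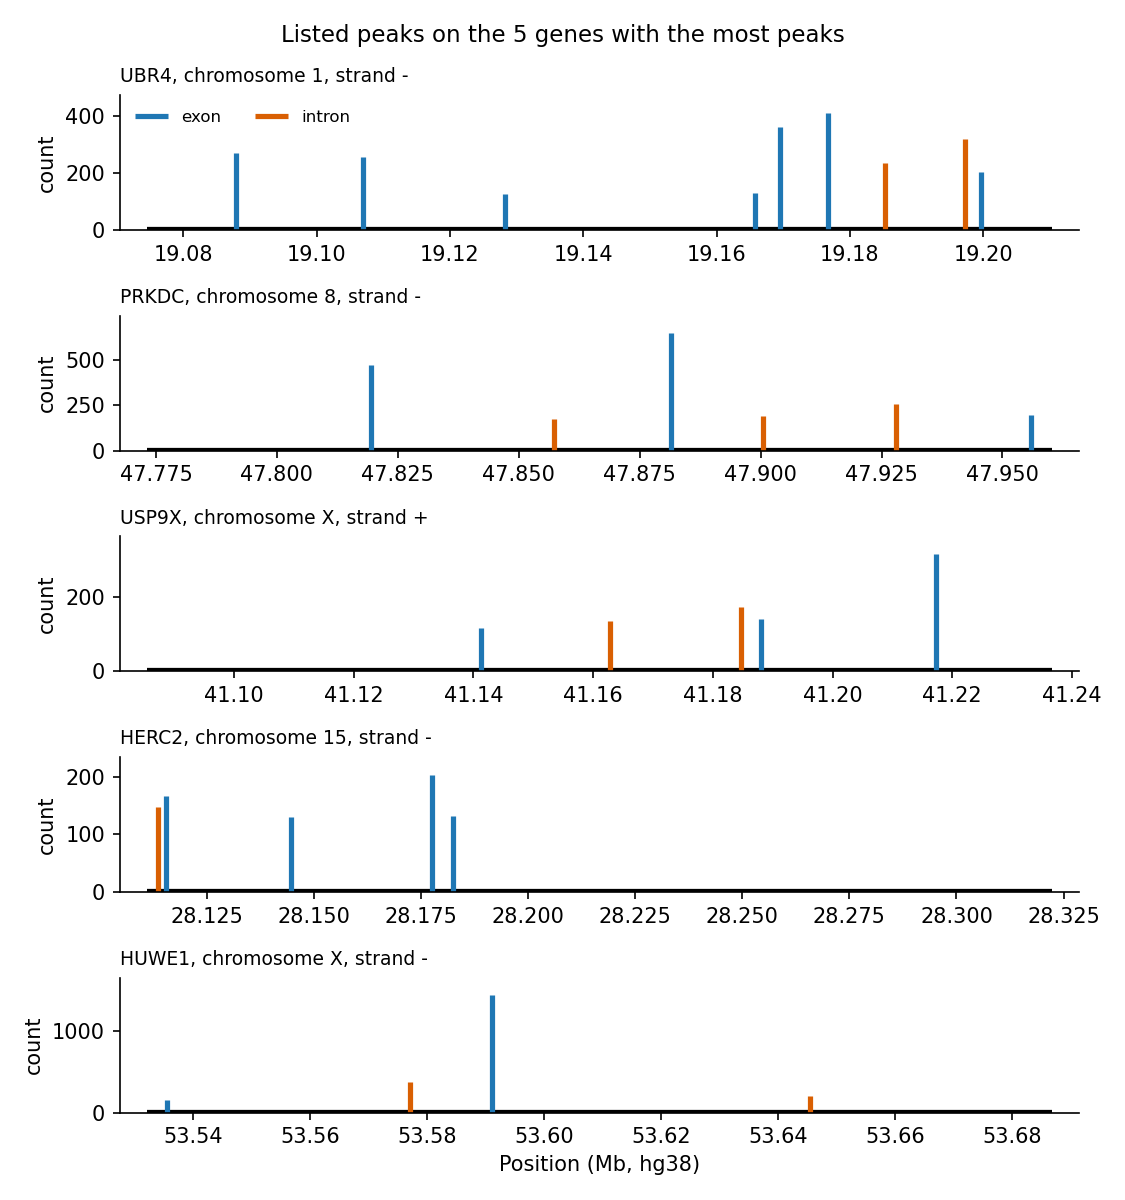
Each panel spans 1 of the 5 genes with the most peaks (black line, position in Mb on hg38), and each vertical line is a listed peak with its count as height, coloured by exon or intron class. UBR4 shows 9 peaks spread over the gene, and HUWE1 has 1 peak of 1442 that stands above its other 3.

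Tight junction and other junction genes were asked about first, as CGN belongs to this structure. Of 37 tight junction genes 1 carried a peak (2.70%, exact 95% interval 0.0684 to 14.2), the scaffold gene TJP1 with a count of 131, against 3.68% of all protein-coding genes (odds ratio 0.728, adjusted exact p = 1, two-sided Fisher's exact test as for every list below). Of 21 adherens junction and desmosome genes 3 had a peak (odds ratio 4.38, adjusted exact p = 0.0911), namely CTNNB1, the gene of beta-catenin, with 322, AFDN, the gene of afadin, with 278 as the highest of 3 peaks, and PKP4 with 136. Of 28 Rho GTPase and actomyosin genes 2 had a peak, the kinases ROCK1 (150) and ROCK2 (119), with an adjusted exact p of 0.442.

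Chromatin and transcription regulators were the list with the smallest p, with a peak on 12 of 36 genes (33.3%, interval 18.6 to 51.0, odds ratio 13.3, adjusted exact p = 8.04e-08). The odds ratio was lower with counts at or above the median (6.34, adjusted exact p = 0.0333) and at a p 10 times stricter (5.88, adjusted exact p = 0.0345). Its highest counts were those of KMT2A (829), POLR2A, the largest subunit of RNA polymerase II (602), the Mediator kinase module gene MED13 (325) and the SWI/SNF gene ARID2 (175). Lipid and cholesterol synthesis had a peak on 6 of 20 genes (30.0%, 11.9 to 54.3, odds ratio 11.3, adjusted exact p = 0.000522). They were led by the sterol-responsive transcription factor SREBF2 (316), DHCR7 (292) and LSS (174), enzymes of late cholesterol synthesis, and HMGCS1 (171), an early enzyme of the pathway. Against the genes of the other fixed lists, without those of other cell types and ductal markers, the chromatin list remained above (odds ratio 4.08, adjusted exact p = 0.0133), and the lipid list did not pass (odds ratio 3.27, adjusted exact p = 0.223).

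Another 7 lists passed against all protein-coding genes, and none of them did against the other fixed lists, where their adjusted exact p lay between 0.291 and 0.810. The focal adhesion, integrin and matrix list had a peak on 8 of 32 genes (odds ratio 8.82, adjusted exact p = 0.0002), with FLNB, an actin crosslinker, at 276 and the integrin genes ITGB5, ITGA2 and ITGA5 at 238, 236 and 233. The mRNA decay and stress granule list had 7 of 34 (odds ratio 6.85, adjusted exact p = 0.00129), with CNOT1, the scaffold of the deadenylase complex, at 338, the nonsense-mediated decay helicase UPF1 at 324, IGF2BP3 at 288 and CAPRIN1 at 214. The cell cycle list had 7 of 42 (odds ratio 5.28, adjusted exact p = 0.00402), with the replication clamp PCNA at 427, CDK6 at 181, and CCNA2 and CENPF both at 153. Its odds ratio fell to 2.52 with counts at or above the median (adjusted exact p = 0.421) and to 2.34 at a p 10 times stricter (adjusted exact p = 0.450). The splicing factor list had 5 of 34 (odds ratio 4.54, adjusted exact p = 0.0283), with PRPF8 at 662, SF3B1 at 353, TRA2B at 266 and HNRNPD at 161.

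The pancreatic cancer driver list had a peak on 4 of 17 genes (odds ratio 8.10, adjusted exact p = 0.0127), SF3B1 at 353, TP53 at 215, ARID1A at 147 and ATM at 121. SF3B1 and ARID1A also belong to the splicing and chromatin lists. KRAS had no listed peak, from which, as for CGN, no limit on its level follows. The microtubule and motor list had 4 of 24 (odds ratio 5.26, adjusted exact p = 0.0348), the cytoskeletal linkers MACF1 (350) and DST (248), and MAP4 (267) and CAMSAP1 (154). The epithelial mesenchymal transition list had 4 of 26 (odds ratio 4.79, adjusted exact p = 0.0411). They were MMP2 (320), TGFBI (153), TGFBR1 (132) and LAMC2 (145), of which LAMC2 also belongs to the focal adhesion list. For the epithelial mesenchymal transition list the odds ratio fell to 2.01 with counts at or above the median (adjusted exact p = 0.707). At a p 10 times stricter it fell to 1.87 (adjusted exact p = 0.703). With random lists matched on genomic span these 3 lists no longer passed, at adjusted permutation p of 0.126, 0.127 and 0.175, although they held 3.85, 3.89 and 3.21 times the genes with a peak that the matched lists gave. With exon and UTR peaks alone, only the chromatin and lipid lists of the 9 passed. The odds ratio was then 8.14 for the driver, 5.42 for the microtubule and 4.95 for the epithelial mesenchymal transition list, near those with all peaks. It was 3.93 for the focal adhesion, 3.67 for both the decay and the splicing list and 1.89 for the cell cycle list, below those with all peaks.

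**Figure D3:**
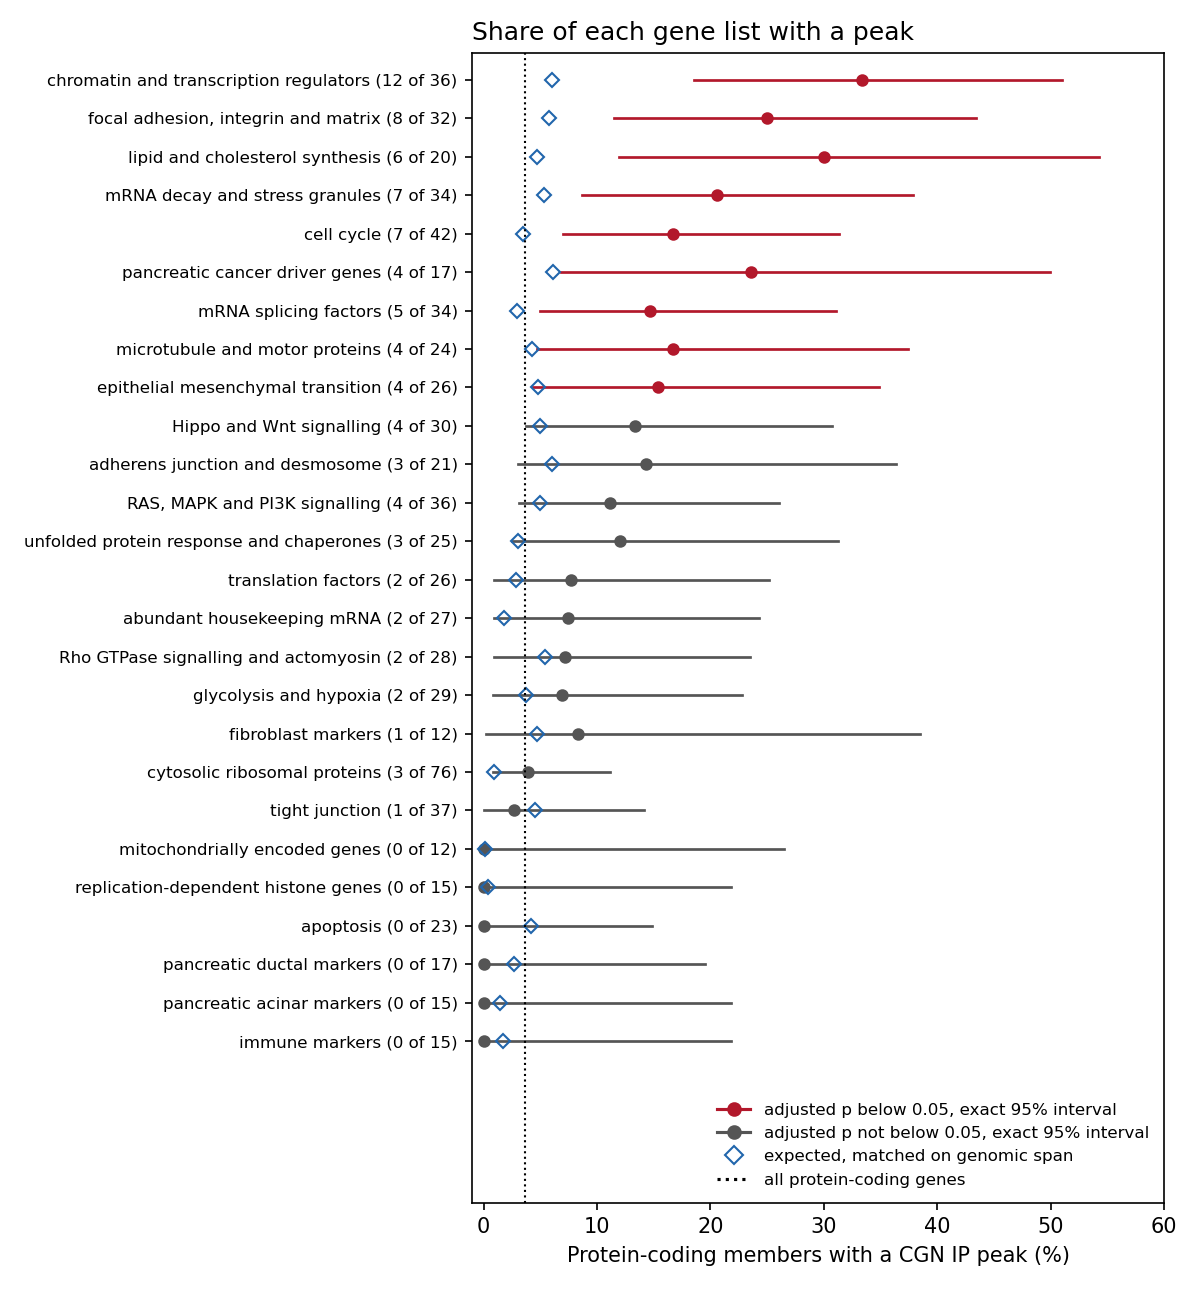
Points give the share (%) of each list's protein-coding members with a peak, with exact 95% intervals, in red where the adjusted p was below 0.05. Diamonds give the share expected from lists matched on genomic span, and the dotted line gives the share of all protein-coding genes, 3.68%. The 9 red lists lie above the line, led by the chromatin list at 33.3%.

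The remaining lists did not pass. The Hippo and Wnt list had a peak on 4 of 30 genes (adjusted exact p = 0.0604), with WWTR1, the gene of the transcriptional coactivator TAZ, at 460, CTNNB1 at 322, TEAD1 at 138 and TCF7L2 at 134. RAS, MAPK and PI3K signalling had 4 of 36 (adjusted exact p = 0.0911), TSC2 at 230, MTOR at 212, PIK3CB at 165 and SPRED1 at 119. The unfolded protein response and chaperone list had 3 of 25 (adjusted exact p = 0.125), CANX, PDIA6 and PDIA3. Lists of abundant mRNAs did not pass either. Of 27 housekeeping genes PKM (906) and ENO1 (120) had a peak, which are also the 2 of 29 glycolysis and hypoxia genes. Of 26 translation factor genes EIF2S1 (162) and EIF4G3 (122) had a peak, with an adjusted exact p of 0.442 for each of these 3 lists. Of 76 ribosomal protein genes 3 had a peak, RPL17 (709), RPS12 (204) and RPL3 (139), with an odds ratio of 1.08 and an adjusted exact p of 1. Lists matched on genomic span gave 0.698 (adjusted permutation p = 0.175). None of 15 replication-dependent histone genes, 23 apoptosis genes, 14 mitochondrially encoded genes, 22 small structural RNAs or 23 long non-coding RNAs on the lists had a peak, and the tested ones among these lists had an adjusted exact p of 1. Among markers of other cells or of pancreatic lineages, 1 of 12 fibroblast genes had a peak (COL1A1, 173, adjusted exact p = 0.523), and none of 17 ductal, 15 acinar or 15 immune genes did. At the share of all protein-coding genes, 0.62 ductal, 0.55 acinar and 0.55 immune genes would have had a peak. Finding none therefore shows neither a deficit nor the absence of such RNA.

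Among genes with a peak, counts were compared between list members and all others for 14 lists. The 3 unfolded protein response genes had a median count of 489 against 171 for the other 738 genes (ratio 2.86, adjusted permutation p = 0.0426), with CANX at 795, PDIA6 at 489 and PDIA3 at 120. This call rested on 3 genes and ended when the log2 difference of 1.52 fell to 0.91 with means (adjusted permutation p = 0.185) and to 0.93 with the mean over the peaks of a gene (adjusted permutation p = 0.239). The other 13 lists did not pass. The 12 chromatin genes had a median of 147.5 against 171 (ratio 0.863, adjusted permutation p = 0.546), a log2 difference of -0.21 that was 0.019 with means, and the 5 splicing genes 266 against 171 (ratio 1.56, adjusted permutation p = 0.283).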

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

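No paired analysis was possible because the deposited list has no value per library, so neither the shared replicate numbers nor leaving out a replicate could be tried. The comparisons of IP with input, the replicate agreement, the base composition of peaks, and the region classes rebuilt from an annotation were likewise not run, since they need values per library, a genome or exon coordinates. Leaving out peaks on the mitochondrial genome or unplaced contigs removes nothing, as none is listed. A background matched on exonic length was replaced by one matched on genomic span, chosen after seeing the data. By construction, the list falls to 465 peaks on 394 genes at a count at or above the median. It falls to 501 peaks on 424 genes at a p 10 times stricter than the largest. Since p followed the count, both settings are cuts on the count at near levels and not independent checks. The exon and UTR share stayed between 63.9% and 66.7%, and the intron share between 33.2% and 36.0%, under all alternatives run. The difference in log2 count passed the threshold only with means, at 0.092 for exon peaks and -0.085 for intron peaks, and kept its sign under the others. The 5' UTR difference of 0.013 turned to -0.026 with 1 peak per gene and to -0.035 with means, never past the threshold, and was not run at the stricter p, which leaves under 10 such peaks. Of the 9 gene lists that passed, 4 did at a count at or above the median, 5 at the stricter p, 2 with exon and UTR peaks alone, 6 matched on genomic span, and 1 against the other fixed lists, each time a subset of the 9. Fewer genes with a peak enter the first 3 of these settings; the cause was not tested further. The chromatin list passed in all 5, with an odds ratio of 13.3 falling to 6.34 and 5.88 in the first 2. There the cell cycle list fell from 5.28 to 2.52 and 2.34 and the epithelial mesenchymal transition list from 4.79 to 2.01 and 1.87, without passing. Calls were also lost at large odds ratios, for the microtubule list (5.26, then 7.23 and 6.70), the driver list (8.10, then 6.73 and 6.24) and, at the median only, the splicing list (4.54, then 4.90). Of the 14 lists compared on count, 1 passed, and 0 did with the mean over peaks, with exon and UTR peaks alone (9 lists, without the unfolded protein response list that had passed) or with means, where 2, 1 and 1 lists had an unadjusted p under 0.05. The unknown depth and the missing input values limit every statement to what is listed.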

Other observations

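Gene families defined by the whole run of letters that opens a symbol were scanned after the lists had been seen, over 277 families of at least 10 protein-coding genes. Nucleoporins of the NUP family carried peaks on 9 of 23 genes (39.1%, odds ratio 17.0, adjusted exact p = 8.31e-06, Fisher's exact test with Benjamini-Hochberg adjustment), where lists matched on genomic span gave 1.38. NUP205 had the highest count, 637, and the others were NUP107, NUP133, NUP153, NUP155, NUP188, NUP210, NUP214 and NUP43. Phosphatase subunit genes whose symbols open with PPP had 11 of 77 genes (odds ratio 4.42, adjusted exact p = 0.00779), among them PPP1CA with a count of 433. The family CDK so defined, not all of it kinases, had 6 of 28 (odds ratio 7.20, adjusted exact p = 0.0252), and one of these, CDK11A, has a near-identical copy. Symbols that open with CDKN form a separate family, with 0 of 10. Genes whose symbols open with EIF, which include the kinase EIF2AK4 beside initiation factors, had 8 of 56 (odds ratio 4.40, adjusted exact p = 0.0378), whereas the translation factor list fixed beforehand had 2 of 26 and did not pass (adjusted exact p = 0.442). Zinc finger genes of the ZNF family lay below the other genes, with 6 of 517 (odds ratio 0.302, adjusted exact p = 0.0367). All 5 passed with span matching too, at adjusted permutation p of 0.0277 for NUP and 0.0462 for the other 4. None of 392 OR genes, olfactory receptors, had a peak (adjusted exact p = 7.78e-05, and 1 with span matching), nor any of 665 uncharacterised genes whose symbols open with LOC (adjusted exact p = 4.37e-09, and adjusted permutation p = 0.0277 with span matching). Expression and exonic length were not part of these tests. Whether the authors' annotation held the LOC genes is not known here, and a gene outside it could not have been listed.

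The tests of genomic span, abundance, short genes, pseudogenes, input bins, predicted transcripts and unspliced RNA below were chosen after the data had been seen, as were the family scan and the background of the other fixed lists.

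The 9 gene lists above the background were set against genomic span, since longer genes offer more bins and genes with a peak had the longer median span. The chromatin list had 12 genes with a peak where the upper limit of the 95% range of matched lists was 5. The focal adhesion list had 8 against 5, the lipid list 6 against 3 and the decay list 7 against 5. The cell cycle list had 7 against 4 and the splicing list 5 against 3. These 6 lists also passed once adjusted over the lists, so span as the whole explanation is argued against for them. The driver and microtubule lists had 4 against 3 each but did not pass once adjusted (adjusted permutation p = 0.126 and 0.127), so span is not excluded for these. The epithelial mesenchymal transition list had 4 against 4, which is 3.21 times the 1.25 expected, so span is not excluded for it and not shown as its cause either. The matching did not cover exonic length, although 63.9% of peaks lay in exons or UTRs, so longer mRNAs stay open for every list. Expression also stays open for every list, because no expression value was used here. Only the chromatin list passed against the other fixed lists (odds ratio 4.08). That pool held other lists that had passed, so it decides nothing for the lists that did not pass there.

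The 27 housekeeping genes, of which 2 had a peak, were looked at because p followed the count alone. Their share of 7.41% (exact 95% interval 0.910 to 24.3) was not below the 3.67% of other protein-coding genes. Lists matched on span gave 0.479 genes on average (95% range 0 to 2). Both backgrounds include genes that PANC-1 cells do not express, so a deficit against expressed genes is not excluded. Against the other fixed lists the share was lower, 7.41% against 12.4% (odds ratio 0.565, adjusted exact p = 0.877, Fisher's exact test). For ribosomal protein genes it was 3.95% against 13.3% (odds ratio 0.268, adjusted exact p = 0.194), and neither list passed. Whether bins were listed by IP count alone stays open, since the list has no value for unlisted genes and the share that such a rule would give is not known. The bound of 50% set for that test and for the pseudogene test rested on no measured value, and neither decides anything. Of the housekeeping, ribosomal and translation genes, 2 of 16 without a named pseudogene had a peak (12.5%) and 5 of 113 with one (4.42%, Fisher's exact p = 0.209), and removal of bins also called in the input could not be tested with 0 input values in the file.

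About 36.0% of peaks were intron-assigned, which for an immunoprecipitate described as mRNA invites a second look. Intron assignment was not more frequent at predicted transcripts, where its odds were 0.850 times those at curated ones (95% interval 0.639 to 1.13, 123 of 365 and 211 of 564 peaks). This does not decide whether the choice of transcript made the intron class, since class and transcript may come from the same choice. Unspliced RNA or DNA could cover introns by length, yet genes with an intron peak did not have measurably longer spans (difference in median log2 span -0.064, p = 0.634, permutation test), which decides nothing. Of 75 genes with peaks of both classes, 71 had no transcript in common between them, so the classes refer to different gene models. Whether intron bins overlap exons of other models stays open without exon coordinates.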
